A study of Mus musculus with 6 samples.

How the data were processed

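Total RNA of cultured mouse ovaries was measured by RNA sequencing in 3 Control (DMSO) and 3 ISRIB libraries, made with a universal RNA-seq kit after column isolation, per the labels' protocols. The authors deposited FPKM values for 26329 genes, with a column per library and replicates not pooled. The submitters' processing notes name fastp, HISAT2, HTSeq, R 3.2.0 and DESeq2 and the mouse build mm10, without roles or order. The annotation, the strand setting of the counting and the library total that the FPKM were scaled by are not given in the sources used here, so reads of overlapping and antisense genes may not be told apart. Whether the replicates came from separate animals or cultures is not stated, so p-values measure the spread between these samples, which may be technical.

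The depth was read from the deposited FPKM themselves. Each value was a whole number of reads times a factor for the library and a factor for the gene, and all genes came out whole in every library (100.0%, tolerance 0.01 read, largest distance 2.4e-04). The library factors differed from those of the recovered totals by at most 0.016%. Totals were 34474821, 37937598 and 38002135 reads in Control and 35949121, 36834799 and 35679814 in ISRIB, and the 10 most abundant genes took 3.63% to 3.88% of them. On simulated reads the recovery was exact for 92.12% of 2906 genes, and for 98.05% of the 1952 with a mean of at least 10 reads. With the recovered totals as library size, the gene factor gave an implied gene length, 3549 bases at the median of the tested genes. It lay within 10% of the longest GENCODE M21 transcript for 40.9% of the tested genes matched by symbol. No pair of replicates came from a single library: the chi-square per gene between replicates was 7.76 to 18.72, beyond sampling noise in every pair. Pearson's r of log2 values was 0.987 to 0.9942 within groups and 0.987 to 0.9937 between groups.

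Groups were taken from the sample titles. The test, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined. FPKM are not counts, so log2(FPKM + 0.5) was tested with limma 3.58.1 in R 4.3.3 (linear model with 2 groups, empirical Bayes with an intensity trend, two-sided, Benjamini-Hochberg adjusted p under 0.05) on the 12922 genes with a mean FPKM of at least 1 over the 6 libraries. Fold changes are on the log2(FPKM + 0.5) scale, which understates those of low genes. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. In data simulated for ISRIB against Control over the 12922 genes, 200 were changed, with noise independent between genes. The fit called 73 of 100 genes changed by 0.5 on the log2 scale and 97 of 100 changed by 1. It called 11 unchanged genes and gave 0 wrong signs.

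Gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 35 lists with at least 5 tested members. Beside it stood camera with an estimated correlation, with which 0 lists passed, and fry. The 25 pathway and quality lists were ISR and ATF4 targets, aminoacyl-tRNA synthetases, eIF2 and its kinases, ER chaperones, mTOR components, KIT and PI3K-AKT components, regulators of primordial follicles, cytosolic ribosomal proteins, cholesterol synthesis, glycolysis, oxidative phosphorylation, mitochondrially encoded genes, proliferation, apoptosis, p53 targets, NRF2 genes, heat shock, hypoxia, interferon, cytokines, immediate early genes, autophagy, extracellular matrix, Hippo-YAP targets and meiotic prophase. The 10 cell type lists were oocytes of all stages, growing oocytes, granulosa, theca, stroma, surface epithelium, endothelium, pericytes and smooth muscle, immune cells, and oviduct and mesonephric epithelium. In data simulated with no correlation between genes a raised list was called and 0 of 50 unchanged lists were. The correlations estimated in the real lists were −0.0397 to 0.938, so that check does not cover correlated lists. Because no gene passed, the named genes are the 5 with the smallest p in each direction, leaving out predicted and clone-named genes, 18 genes fixed in advance and up to 4 members of each list with the smallest p. Not every gene that the rule names is printed. Genes outside this rule were chosen after their values were seen.

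The alternatives fixed in advance were pseudocounts of 0.1 and 1, no filter on low values and a mean FPKM of at least 5, TPM rescaling, median-of-ratios scaling, quantile normalization, no intensity trend, robust empirical Bayes, array weights, the replicate number as a block, leaving out each library, and a minimum absolute log2 fold change of 1. Those added after seeing the data were limma's voom on the recovered reads, removal of a loess trend (span 0.5) on gene length or on length and GC content from each library, voom with the length correction, and the immediate early score as a covariate. Gene positions and GC content came from GENCODE M21 (GRCm38, the same build as mm10), matched by symbol, with a GC value for 98.5% of the tested genes.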

Results

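RNA sequencing was carried out on 6 libraries of cultured mouse ovary. In 3 of them the ovaries had been cultured with the solvent DMSO (Control) and in the other 3 with ISRIB, a small molecule that binds the translation initiation factor eIF2B and relieves the brake that the integrated stress response (ISR) puts on protein synthesis. The values were the authors' FPKM (fragments per kilobase of gene, scaled to the size of the library) for 26329 genes. Whole read numbers worked back from the FPKM values added up to 34474821 to 38002135 reads per library, and an FPKM of 1 in a gene of median length stood for about 122.3 reads in the shallowest library. Dose, length of culture and the age of the ovaries are not given in the sources used here. The study's title places the comparison in the question of whether inhibiting the ISR activates primordial follicles, the resting stage of the oocyte reserve, through the mTOR pathway.

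Genes induced by low oxygen, enzymes of glycolysis, chaperones of the endoplasmic reticulum (ER) and cytosolic ribosomal protein genes were higher in ISRIB as groups, with median log2 fold changes of 0.33, 0.25, 0.22 and 0.18 on the log2(FPKM + 0.5) scale. These calls are from camera with a preset correlation, and each list had an adjusted p = 0.493 with an estimated correlation. The ribosomal median was 0.08 after a correction for gene length. Endothelial markers and KIT and PI3K-AKT signalling genes were lower as groups, with medians of −0.13 and −0.05 (adjusted p = 0.691 and 0.493 with an estimated correlation). The KIT call was lost after the length correction, with a median of −0.02 (adjusted p = 0.148). No single gene passed the test. Of 12922 genes with a mean FPKM of at least 1, 0 had a limma adjusted p under 0.05, and the smallest adjusted p was 0.0608. At an unadjusted p under 0.05 there were 2125 genes, of which 1126 were higher and 999 lower in ISRIB, where 646 would be expected with no difference. The 3 ISRIB libraries lay all above the 3 Control libraries for 1391 genes and all below for 1555, together 22.8% of the genes tested, where chance gives 10%. With limma's voom on the recovered reads, an alternative chosen after seeing the data, 120 genes passed, 40 higher and 80 lower, and with the length correction 23 passed, 10 higher and 13 lower.

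The 5 genes with the smallest p among those higher in ISRIB had adjusted p values of 0.0608 to 0.0618 in limma. Vegfa, which codes for the main growth factor of blood vessels (chromosome 17, 46016993 to 46032369, minus strand, GRCm38), measured 83.7 ± 7.21 FPKM in Control and 135 ± 12.8 in ISRIB (mean ± SD, n = 3 each), a log2 fold change of 0.69 (SE 0.0826). P4ha2, a collagen prolyl hydroxylase subunit (chromosome 11, 54100095 to 54131665, plus strand), went from 13.7 ± 1.47 to 22.1 ± 1.16 FPKM, a log2 fold change of 0.67 (SE 0.0820). Pdia4, a protein disulfide isomerase of the ER (chromosome 6, 47796141 to 47813430, minus strand), had 99.6 ± 2.12 and 132 ± 6.73 FPKM and a log2 fold change of 0.40 (SE 0.0475). The other 2 were noncoding genes that host small nucleolar RNAs in their introns. Gas5 (chromosome 1, 161034422 to 161038539, plus strand) had 127 ± 8.85 FPKM in Control and 181 ± 7.17 in ISRIB, and Snhg12 (chromosome 4, 132308623 to 132311024, plus strand) had 32.3 ± 0.336 and 46.4 ± 3.77 FPKM, with log2 fold changes of 0.51 for both. In voom on the recovered reads these 5 genes had adjusted p values of 0.0189 to 0.0298. With the length correction Snhg12 no longer passed there (log2 fold change 0.39, adjusted p = 0.109), and the other 4 had adjusted p values of 0.0312 to 0.0408.

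Among the genes lower in ISRIB, the 5 with the smallest p had limma adjusted p values of 0.0608 to 0.0770. Eif4ebp2, a repressor of translation that mTOR phosphorylates (chromosome 10, 61428491 to 61452661, minus strand), measured 33.5 ± 0.488 FPKM in Control and 25.9 ± 0.254 in ISRIB, a log2 fold change of −0.36 (SE 0.0400). Xdh, xanthine dehydrogenase (chromosome 17, 73883895 to 73950196, minus strand), had 3.11 ± 0.152 and 1.54 ± 0.160 FPKM, a log2 fold change of −0.83 (SE 0.0969). The type XII collagen gene Col12a1 (chromosome 9, 79598991 to 79718831, minus strand) had 15.6 and 10.5 FPKM, a log2 fold change of −0.55, and Gna12, a G protein alpha subunit (chromosome 5, 140758408 to 140830431, minus strand), had 83.8 and 69.6 FPKM, a log2 fold change of −0.27. Rpl21 (chromosome 5, 146832890 to 146837032, plus strand) was at 12.3 and 5.18 FPKM, a log2 fold change of −1.15. Its level was far below the 555 ± 16.4 FPKM of Rpl24 in Control, and ribosomal protein genes have many near-identical processed copies that can take their reads, so its value is uncertain.

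**Figure D1:**
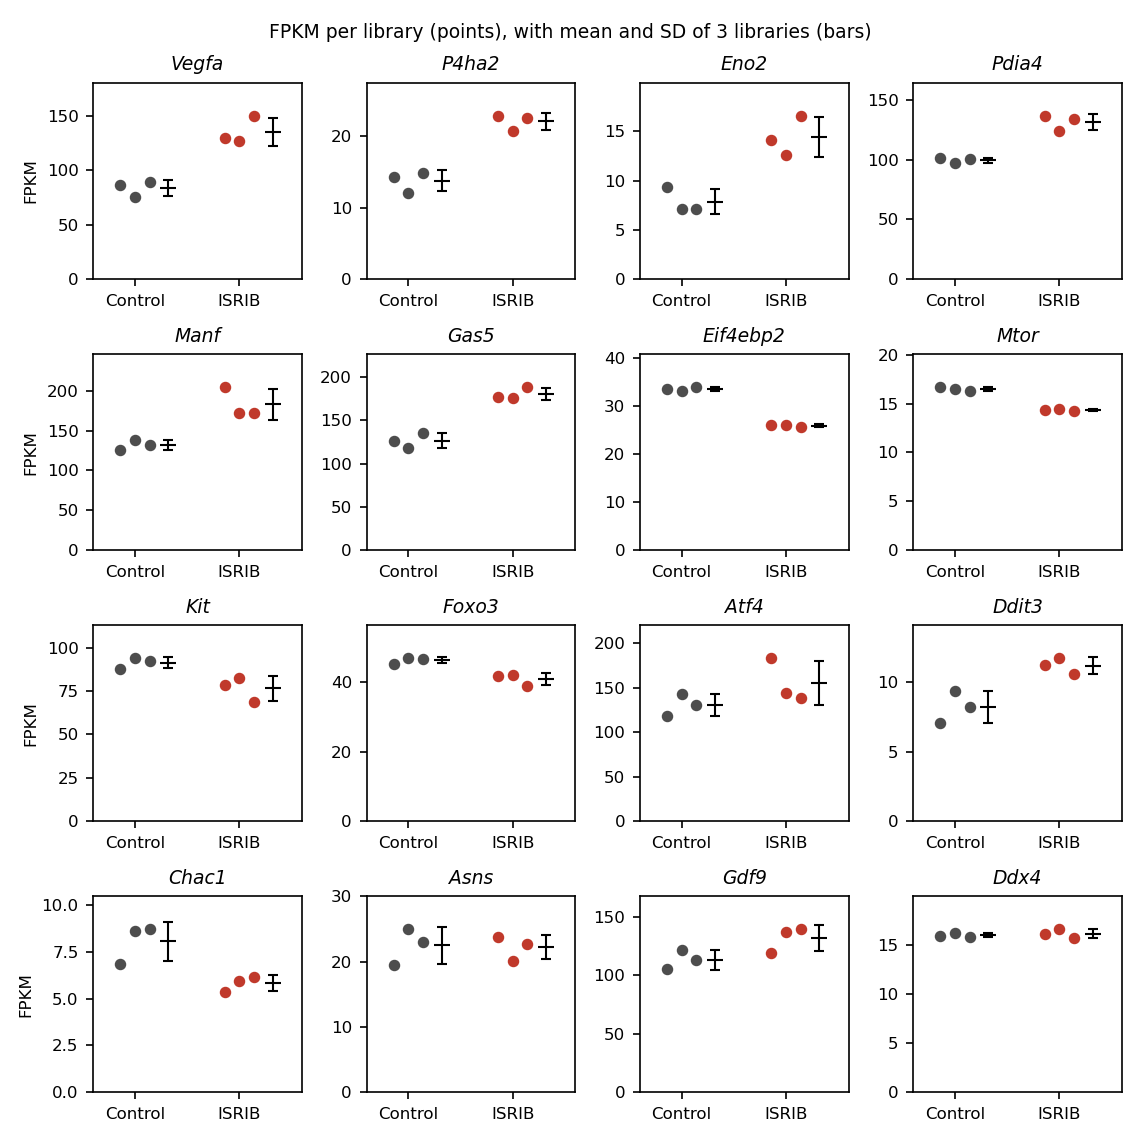
FPKM of 16 genes in each of the 3 Control and 3 ISRIB libraries (points), with the mean and SD of each group (bars), each y axis starting at 0. Vegfa lies at 83.7 FPKM on average in Control and 135 in ISRIB, with all ISRIB libraries above all Control libraries, while Asns and Ddx4 overlap between the groups.

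Genes that the hypoxia-inducible factors raise formed the group with the largest median difference among those that passed. Of 20 members measured, 19 were higher in ISRIB, 16 had all ISRIB libraries above all Control libraries, and the group rose with a camera adjusted p of 6.04e-12 (adjusted p = 0.493 with an estimated correlation). Besides Vegfa and P4ha2, it included Ndrg1 (log2 fold change 0.46, adjusted p = 0.0832) and Ankrd37 (0.60, adjusted p = 0.0832). None of its members passed over all genes tested, and 15 passed when adjusted over the list alone. Glycolysis rose with a camera adjusted p of 1e-10 (adjusted p = 0.493 with an estimated correlation). There 19 of 20 genes were higher, 15 with no overlap between groups, and 16 passed when adjusted over the list alone. The neuronal-type enolase Eno2 had 7.86 ± 1.29 FPKM in Control and 14.4 ± 2.03 in ISRIB, a log2 fold change of 0.84 (SE 0.128, adjusted p = 0.0832). Gpi1, Pfkp and Aldoa, which act in the upper part of the pathway, had log2 fold changes of 0.24, 0.26 and 0.29. The hypoxia and glycolysis lists share some genes.

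All 25 chaperone and ER-associated degradation genes measured were higher in ISRIB, 19 of them with all ISRIB libraries above all Control libraries, and the group rose with a camera adjusted p of 2.32e-14 (adjusted p = 0.493 with an estimated correlation). When adjusted over the list alone 17 passed, and over all genes 0 did. Next to Pdia4, the ER chaperone Pdia6 had a log2 fold change of 0.30, the ER-resident growth factor Manf 0.46 and the ubiquitin ligase Syvn1 0.26 (adjusted p = 0.0832 for each). In fry, which asks whether the members move one way on balance, the adjusted p was 0.0976 for this list, hypoxia, glycolysis and ribosomal proteins alike.

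**Figure D2:**
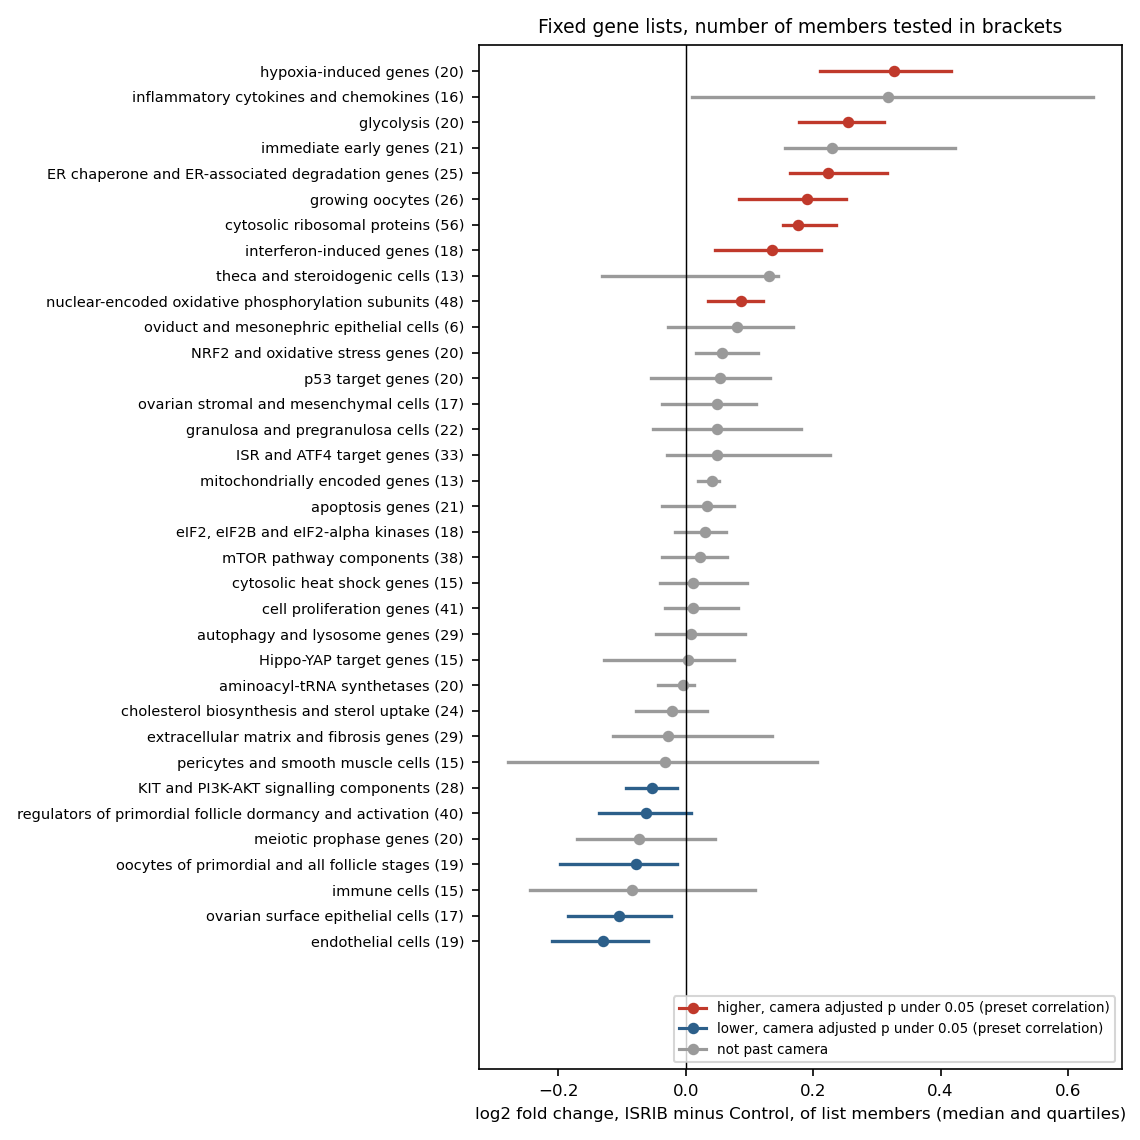
Median log2 fold change (point) and quartiles (line) of the members of each of the 35 fixed gene lists with at least 5 tested members. In color are the 7 lists that were higher and the 5 that were lower in ISRIB in camera with the preset correlation. They run from hypoxia-induced genes at 0.33 to endothelial markers at −0.13. With an estimated correlation 0 lists passed.

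Cytosolic ribosomal protein genes, which are short and abundantly expressed, were higher in 55 of 56 cases, 49 with no overlap between groups (camera adjusted p = 2.13e-25, and 0.493 with an estimated correlation). Rpl21 is not in this list. In this list 50 passed when adjusted over the list alone and 0 over all genes. Rpl24 had 555 ± 16.4 and 657 ± 19.1 FPKM, Rpl38 204 and 244 FPKM, and Rps25 505 and 602 FPKM, with log2 fold changes of 0.24, 0.25 and 0.25. The nuclear-encoded subunits of oxidative phosphorylation rose by a smaller step, with a median of 0.09 and 42 of 48 higher (adjusted p = 7.32e-06, and 0.493 with an estimated correlation). Ndufa5 had a log2 fold change of 0.27 (adjusted p = 0.111) and Atp5o 0.15 (adjusted p = 0.161). Over all genes tested, fold change went down with gene length, with a Spearman rho of −0.361 and a Pearson r of −0.318 across genes, which are not independent replicates. Once this trend was removed from each library, the median of the ribosomal protein genes was 0.08 (adjusted p = 9.19e-13), and that of the oxidative phosphorylation subunits was −0.00, with no call left (adjusted p = 0.871). Quantile normalization gave the ribosomal protein genes a median of 0.07 and glycolysis 0.16, and the subunits had 0.04 there and 0.03 after TPM rescaling, which set the median of all genes to −0.05. The 13 mitochondrially encoded genes had a median of 0.04, a mean of −0.01 and a median of −0.01 after TPM rescaling (adjusted p = 0.567, with medians of 0.01 to 0.08 when single libraries were left out).

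**Figure D3:**
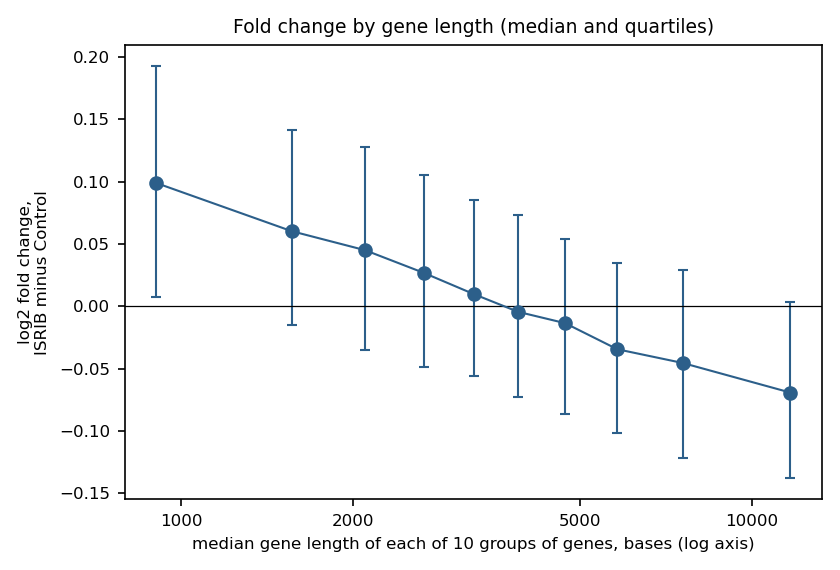
Log2 fold change against gene length for the 12922 tested genes in 10 groups of rising length (median and quartiles, log axis for length in bases). The median falls from 0.10 in the shortest genes, with a median length of 903 bases, to −0.07 in the longest genes, with 11684 bases.

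Transcripts that the ISR itself controls did not pass the test as a group. The ISR and ATF4 target list had a median log2 fold change of 0.05, with 22 of 33 members higher (camera adjusted p = 0.137), and the 20 aminoacyl-tRNA synthetases, which ATF4 also drives, had a median of −0.00 (adjusted p = 0.753). Atf4, the transcription factor at the center of the response, measured 131 ± 12.6 FPKM in Control and 155 ± 24.7 in ISRIB (log2 fold change 0.24, SE 0.112, adjusted p = 0.334, and 0.11 without ISRIB replicate 1). Ddit3, which codes for the stress factor CHOP, had 8.23 ± 1.15 and 11.2 ± 0.582 FPKM (0.43, SE 0.0970, adjusted p = 0.119), and the glutathione-degrading enzyme Chac1 had 8.04 ± 1.05 and 5.82 ± 0.414 FPKM (−0.43, SE 0.101, adjusted p = 0.119). Both had all ISRIB libraries on one side of Control. Asns, asparagine synthetase, had a log2 fold change of −0.02 (0.06 without Control replicate 2), Trib3 of 0.16 (0.10 without ISRIB replicate 1), Stc2 of 0.24 and the synthetase Lars of −0.11. Of the 33 targets, 1 higher and 1 lower passed when adjusted over the list alone. After TPM rescaling the ISR list had a median of −0.00, and that of the eIF2 genes was −0.02. Without Control replicate 2 the ISR list had a median of 0.06 and an adjusted p of 0.0129, and without ISRIB replicate 2 a median of 0.10 and an adjusted p of 0.00948. The median was 0.03 without Control replicate 1 or without ISRIB replicate 1 (adjusted p = 0.439 and 0.873). The 18 genes of eIF2, eIF2B and the eIF2-alpha kinases had a median of 0.03 (adjusted p = 0.470, and medians of 0.01 to 0.06 when single libraries were left out), among them Eif2b5, the catalytic subunit of ISRIB's target complex, at −0.02 (95% interval −0.12 to 0.08) and the phosphatase subunit Ppp1r15a at 0.38 (adjusted p = 0.403, and 0.14 without ISRIB replicate 1).

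Components of the mTOR pathway went both ways. Their median was 0.02, but −0.03 after TPM rescaling and −0.01 after quantile normalization or without Control replicate 2. Camera's direction was down (adjusted p = 0.988), with 22 of 38 members higher and 16 lower. Mtor had 16.5 ± 0.224 FPKM in Control and 14.3 ± 0.0955 in ISRIB (log2 fold change −0.20, SE 0.0448, adjusted p = 0.119), Rptor −0.16 and the GTPase Rheb, which activates mTOR, 0.17. With Eif4ebp2 at −0.36, 2 members passed when adjusted over the list alone, both lower. Rps6, whose protein is phosphorylated downstream of mTOR, had 482 and 523 FPKM (0.12, adjusted p = 0.261), and −0.06 after quantile normalization. Mtor and Rptor are long (8701 and 8338 bases) and Rheb and Rps6 short (1540 and 1411 bases), so their directions follow the trend with gene length. Eif4ebp2, at 1808 bases, went against that trend. In fry's mixed test, which asks whether members differ in either direction, the list had an adjusted p of 9.09e-06, and 12 of the 35 lists passed that test.

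KIT and PI3K-AKT signalling genes fell as a group, with 23 of 28 members lower and a camera adjusted p of 0.00406. With an estimated correlation the adjusted p was 0.493, and it was the only list past fry's directional test (adjusted p = 0.00535). After the length correction its median was −0.02 and the call was lost (adjusted p = 0.148, 0.149 in voom with that correction and 0.178 after correction for length and GC content), and after TPM rescaling the median was −0.11. Kit, the receptor on oocytes, had 91.4 ± 3.23 FPKM in Control and 76.6 ± 7.25 in ISRIB (log2 fold change −0.26, SE 0.0697, adjusted p = 0.145). Its ligand Kitl, made by granulosa cells, had 35.3 ± 3.56 and 28.3 ± 4.63 FPKM (−0.32, SE 0.121, adjusted p = 0.245, and −0.19 without ISRIB replicate 3). Foxo3, which holds primordial follicles dormant, had a log2 fold change of −0.18 (adjusted p = 0.134), the kinase Pdpk1 of −0.26 (adjusted p = 0.0995) and Phlpp1 of −0.16. Kit, Kitl, Foxo3 and Pdpk1 had all ISRIB libraries below all Control libraries. Adjusted over the list alone, 1 member passed. The regulators of follicle dormancy and activation, which hold several of these genes, had a median of −0.06 with 30 of 40 lower (adjusted p = 0.0144, and 0.554 with an estimated correlation). Without Control replicate 2 that list's median was −0.05 and its adjusted p 0.0880, and after TPM rescaling the median was −0.12. Its scores overlapped between the groups (exact permutation p = 0.5), with ISRIB replicates 1 and 2 within the Control range.

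Markers of growing oocytes were higher and markers of oocytes of all follicle stages lower. Of 26 growing-oocyte genes 23 were higher, with a median of 0.19 and a camera adjusted p of 3.56e-05 (adjusted p = 0.691 with an estimated correlation). After correction for length and GC content the median was 0.12. The score of ISRIB replicate 1 lay below those of Control replicates 2 and 3 (exact permutation p = 0.3), and those of the other ISRIB libraries lay above all Control libraries. Gdf9, an oocyte growth factor, had 113 ± 8.50 FPKM in Control and 132 ± 10.9 in ISRIB (log2 fold change 0.22, adjusted p = 0.219), and the zona pellucida gene Zp3 had 390 and 447 FPKM (0.20, adjusted p = 0.215). Ooep, Npm2 and Oas1e had log2 fold changes of 0.26, 0.22 and 0.26 and the apoptosis regulator Bcl2l10 of 0.40. Of the 19 markers of oocytes of all stages, 15 were lower, with a median of −0.08 and an adjusted p of 0.0415 (0.885 with an estimated correlation). Single libraries decided this call. Its adjusted p was 0.659 without ISRIB replicate 3 (median −0.00), 0.393 without Control replicate 2 (median −0.04) and 0.0508 without Control replicate 3 (median −0.10), while the median was −0.13 without ISRIB replicate 2. TPM rescaling (median −0.13, adjusted p = 0.0515) and array weights (−0.05, adjusted p = 0.0923) also ended it. The scores overlapped between the groups (exact permutation p = 0.5). The germ cell helicase Ddx4 had 16.0 ± 0.196 and 16.2 ± 0.442 FPKM (0.01, 95% interval −0.09 to 0.12, and −0.04 after TPM rescaling), Tdrd9 a log2 fold change of −0.40 and Tdrd1 −0.22 (−0.12 without ISRIB replicate 3). Meiotic prophase genes had a median of −0.07 (adjusted p = 0.262), −0.14 without ISRIB replicate 2 (adjusted p = 0.0288) and −0.03 without ISRIB replicate 3, with the synaptonemal complex gene Syce3 at −1.02 and a low level of 1.99 ± 0.337 FPKM in Control.

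Endothelial markers fell, with 16 of 19 lower and a camera adjusted p of 6.67e-04 (adjusted p = 0.691 with an estimated correlation). Cdh5, the cadherin of endothelial junctions, had 42.3 and 35.0 FPKM (log2 fold change −0.27, adjusted p = 0.119), the VEGF receptor Kdr −0.22 and Eng −0.20. Without ISRIB replicate 1 the median was −0.06 and the adjusted p 0.0693, and after TPM rescaling the median was −0.20. Ovarian surface epithelial markers had a median of −0.11 with 15 of 17 lower and an adjusted p of 0.0425 (0.691 with an estimated correlation). The adjusted p was 0.494 without Control replicate 1 (median −0.02), 0.112 without ISRIB replicate 2, and 0.0569 to 0.105 with array weights, voom, TPM rescaling, the immediate early covariate or a mean FPKM of at least 5. The median was −0.16 after the length correction, the scores overlapped (exact permutation p = 0.2), and Lgr5 and Pkhd1l1 had log2 fold changes of −0.45 and −0.31. Pericyte and smooth muscle markers were split. Their median was −0.03 (adjusted p = 0.191, with −0.06 to −0.02 when single libraries were left out), yet Pdgfrb (−0.33, adjusted p = 0.0799), Abcc9 (−0.44), Mcam (−0.34) and Cspg4 (−0.30) were all lower, and 4 lower and 1 higher passed when adjusted over the list alone. Granulosa and pregranulosa markers had a median of 0.05, and −0.00 after TPM rescaling (adjusted p = 0.988, with 0.02 to 0.06 when single libraries were left out). Foxl2 was at 148 ± 5.48 and 148 ± 13.5 FPKM (log2 fold change −0.01, 95% interval −0.16 to 0.15, and 0.04 without ISRIB replicate 1), Amh at 97.0 ± 30.5 and 115 ± 22.5 FPKM (log2 fold change 0.28, and 0.02 without Control replicate 1), Inha at 0.45 (0.27 without ISRIB replicate 3), and the monoamine transporter Slc18a2 at 29.1 ± 5.49 and 14.2 ± 2.44 FPKM (SE of the log2 fold change 0.158, adjusted p = 0.0832). Medians were 0.13 for theca and steroidogenic cells, 0.05 for stromal cells, −0.09 for immune cells and 0.08 for oviduct and mesonephric epithelium, with adjusted p values of 0.956, 0.848, 0.261 and 0.956. Immune markers had −0.17 and an adjusted p of 0.0279 after the length correction, and for oviduct markers camera's direction was down and the median −0.08 without ISRIB replicate 3. The stromal median was −0.02 without ISRIB replicate 3. Leaving out single libraries took the theca median as low as 0.01 and the immune median from −0.16 without ISRIB replicate 1 to −0.01 without Control replicate 3. Only 4 red blood cell and 4 adipocyte markers had a mean FPKM of at least 1, too few for the list test. All 8 had higher means in ISRIB. Ahsp (0.901 FPKM in Control and 1.58 in ISRIB) and Pparg (0.846 and 1.38) reached that mean only through the ISRIB libraries. For them the filter itself favored a rise. Hbb-bs had 13.8 ± 3.25 FPKM in Control and 57.9 ± 60.9 in ISRIB, with 128 in ISRIB replicate 1 (adjusted p = 0.269). Hba-a1 had a log2 fold change of 0.82 (0.18 without ISRIB replicate 1) and Hbb-bt of 0.60 (−0.30 without ISRIB replicate 1). Ahsp had 0.60 (0.36 to 0.77 when single libraries were left out). The adipocyte genes Fabp4, Lpl, Pparg and Plin1 had 0.45, 0.19, 0.51 and 0.26 (0.00 for Plin1 without ISRIB replicate 3), with Fabp4 at an adjusted p of 0.0987. Adjusted over the list alone, 0 of the red blood cell genes and Fabp4, Lpl and Pparg passed. All ISRIB libraries lay above all Control libraries for Hbb-bs, Ahsp, Fabp4 and Lpl.

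Interferon-induced genes rose with a median of 0.13, 15 of 18 higher and a camera adjusted p of 0.00510 (adjusted p = 0.691 with an estimated correlation). B2m, a subunit of class I histocompatibility proteins, had 285 and 327 FPKM (log2 fold change 0.20), Bst2 0.27 and Gbp3 0.46. Without ISRIB replicate 2 the median was 0.06 and the adjusted p 0.111. The median was 0.08 without Control replicate 1, 0.20 without ISRIB replicate 1 or with array weights, and 0.09 after TPM rescaling or the length correction. Immediate early genes (median 0.23, adjusted p = 0.0713) and inflammatory cytokines (median 0.32, adjusted p = 0.406) had large medians with large differences within groups. The immediate early score stood 0.91 above the mean of the 6 libraries in ISRIB replicate 1 and 0.39 above it in Control replicate 2, and below it in the other libraries. Without ISRIB replicate 1 these medians were −0.10 and −0.42. Without ISRIB replicate 3 the adjusted p was 3.82e-04 for immediate early genes and 0.0240 for cytokines. For immediate early genes it was also 2.49e-05 without Control replicate 2, 0.00302 without ISRIB replicate 2, 0.00342 after TPM rescaling, 0.0386 after quantile normalization, and 0.0289 to 0.0443 with voom or the length corrections.

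Proliferation genes had a median of 0.01, and −0.04 after TPM rescaling (adjusted p = 0.848), with Mki67 at 23.5 ± 1.03 and 23.9 ± 0.805 FPKM (log2 fold change 0.02, and −0.03 after TPM rescaling). Apoptosis genes (0.03, and −0.02 after TPM rescaling, adjusted p = 0.416) and p53 targets (0.05, and −0.00 without ISRIB replicate 1, adjusted p = 0.442) share Bax, which had a log2 fold change of 0.17 (adjusted p = 0.128). The medians were 0.06 for NRF2 and oxidative stress genes, 0.01 for cytosolic heat shock genes and −0.02 for cholesterol synthesis, with adjusted p values of 0.113, 0.956 and 0.567. The NRF2 list's adjusted p was 0.0196 without Control replicate 2, 0.0310 without ISRIB replicate 2 and 0.0279 without ISRIB replicate 3, but 0.385 with a median of 0.01 without Control replicate 3 and 0.744 without ISRIB replicate 1. The heat shock median was −0.04 after TPM rescaling, and the cholesterol median was 0.04 without ISRIB replicate 3. Medians were 0.01 for autophagy and lysosome genes, −0.03 for extracellular matrix genes, whose mean was 0.02, and 0.00 for Hippo-YAP targets, where camera's direction was down, with adjusted p values of 0.262, 0.191 and 0.521. After TPM rescaling the autophagy median was −0.04 and the Hippo-YAP median −0.05. The matrix list had an adjusted p of 0.00434 after quantile normalization, 0.0400 with array weights and 0.0345 without ISRIB replicate 3, and medians of 0.01 and 0.02 after the corrections for length and for length and GC content. In the matrix list Timp3, an inhibitor of matrix proteases, had a log2 fold change of −0.22 (adjusted p = 0.113), and it and Col12a1 passed when adjusted over the list alone.

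**Figure D4:**
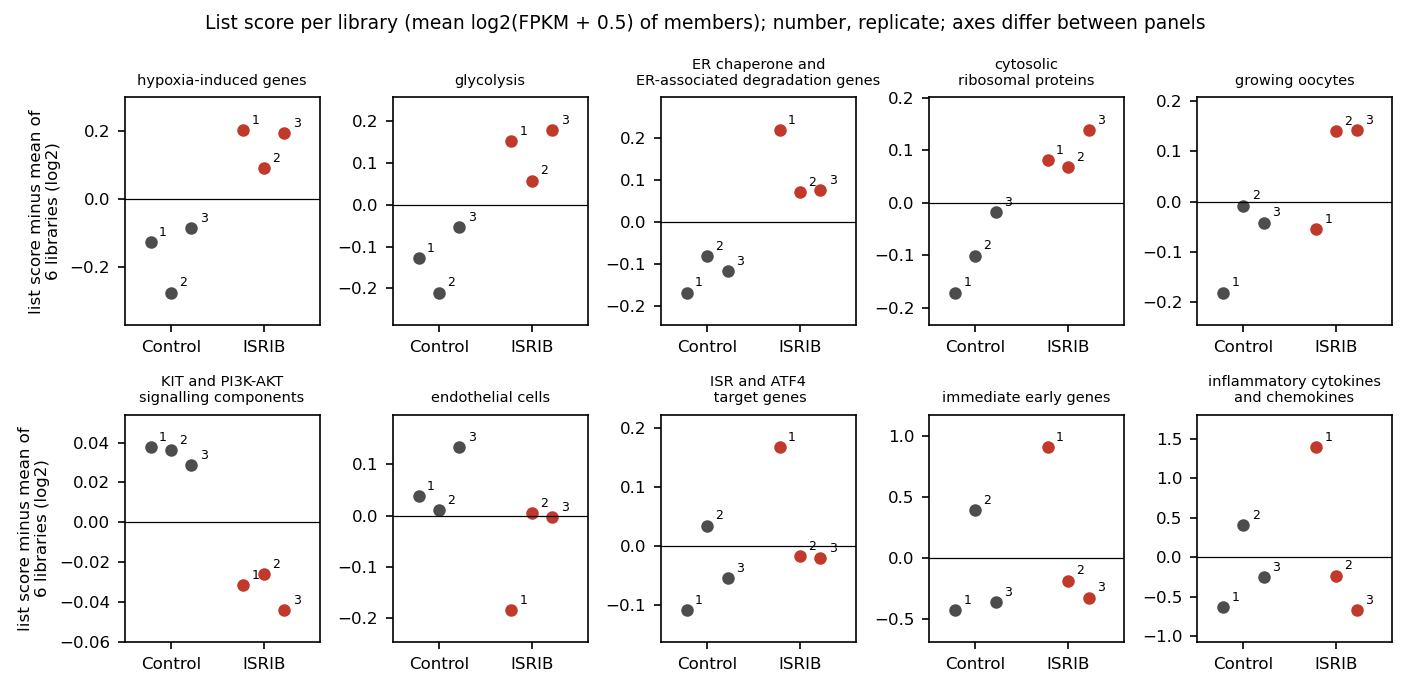
Score of 10 gene lists in each library, as the mean log2(FPKM + 0.5) of the members minus the mean over the 6 libraries, with replicate numbers beside the points. The hypoxia, glycolysis, ER chaperone, ribosomal protein, KIT and endothelial scores separate the 3 ISRIB from the 3 Control libraries. Each has an exact permutation p = 0.1, two-sided, the smallest that 3 against 3 can give. The endothelial score does so narrowly, with 0.0052 in ISRIB replicate 2 and 0.0101 in Control replicate 2. The immediate early score is highest in ISRIB replicate 1.

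In the library scores, no list could pass an exact permutation test, whose smallest p with 3 libraries against 3 is 0.1. For hypoxia-induced genes the score was 4.24 ± 0.0992 in Control and 4.56 ± 0.0623 in ISRIB, for ER chaperones 5.95 ± 0.0440 and 6.20 ± 0.0849, and for KIT and PI3K-AKT genes 4.28 ± 0.00488 and 4.21 ± 0.00911 (exact permutation p = 0.1 for each, and 0.389 after Benjamini-Hochberg adjustment over the 35 lists).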

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

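The tests chosen only after the data were seen were voom on the recovered reads, the corrections for gene length and for length and GC content, voom with the length correction, and the immediate early score as a covariate. Whether a list reversed was read from the sign of its median, and for lists past the test also from camera's direction, a choice made after both readings had been seen: it counts 55 reversals among the list values, and camera's direction for every list would count 69. Over all alternatives 1939 gene values kept their direction and their side of the threshold, 82 came past it and 14 reversed. Of the list values 720 kept both, 22 came past the threshold, 41 fell short of it and 55 reversed. Where no cause is given below, the cause was not tested.

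In limma 0 genes passed, and 2125 had an unadjusted p under 0.05. A mean FPKM of at least 5, with fewer genes tested, gave 8 genes, 5 higher and 3 lower. Array weights gave 16, 8 higher and 8 lower. Voom on the recovered reads gave 120, 40 higher and 80 lower, with the length correction 23, 10 higher and 13 lower, and the immediate early covariate gave 11, 10 higher and 1 lower. The smallest adjusted p over the alternatives went from 0.0189 in voom to 0.274 without Control replicate 2. Leaving out each library gave 0 genes every time, and 1487 to 2429 genes with an unadjusted p under 0.05.

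The labels do not say whether equal replicate numbers mark paired samples. Same-number libraries had correlations of deviations of −0.19, −0.0909 and 0.192, and 3 libraries per group are too few to settle it. With the replicate number as a block the count of genes moved from 0 to 11, with 9 higher and 2 lower.

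Of the 8 pathway lists past camera with a preset correlation, 0 passed with an estimated correlation and 1 passed fry. Of the 4 cell type lists 2 passed after TPM rescaling, 2 with array weights, 0 with an estimated correlation and 0 in fry. Under the 22 alternatives of scaling, filter, fit or library, hypoxia-induced genes kept their call with medians of 0.266 to 0.397, glycolysis with 0.156 to 0.295, ER chaperones with 0.167 to 0.259, ribosomal proteins with 0.0654 to 0.222 and growing oocytes with 0.121 to 0.263.

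Medians that reversed after TPM rescaling, which shifted the median of all genes from 0.00539 to −0.0462 and so took small positive medians below 0, were −0.00105 for ISR and ATF4 targets, −0.0207 for eIF2, eIF2B and eIF2-alpha kinases, −0.0276 for mTOR components, −0.0115 for mitochondrially encoded genes, −0.0409 for proliferation, −0.0176 for apoptosis, −0.0408 for heat shock, −0.0449 for autophagy, −0.0488 for Hippo-YAP targets and −0.00289 for granulosa cells. The log2 fold changes of Ddx4 and Mki67 became −0.0386 and −0.0283. Quantile normalization gave −0.0140 for mTOR components, −0.0302 for heat shock, −0.0175 for autophagy and −0.0582 for Rps6.

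The length correction turned 6 medians. Oxidative phosphorylation subunits had −0.00196, mitochondrially encoded genes −0.0418, proliferation −0.00814, heat shock −0.0229, autophagy −0.0214 and extracellular matrix 0.00839. With GC content also corrected the subunits had −0.00787, proliferation −0.0122, NRF2 genes −0.000515, heat shock −0.0296, autophagy −0.0176 and extracellular matrix 0.0168. In voom with the length correction the subunits had −0.00857, mitochondrially encoded genes −0.0466, proliferation −0.0143, heat shock −0.0124, autophagy −0.0271 and extracellular matrix 0.0108. A mean FPKM of at least 5 gave −0.00271 for heat shock and −0.00646 for Hippo-YAP targets, and array weights gave the latter −0.00597. With the immediate early covariate heat shock had −0.0131, cytokines −0.0782, Hippo-YAP targets −0.0163 and Foxl2 0.0184.

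Leaving out single libraries turned some small values. The ranges were −0.114 to 0.0617 for Asns, −0.00614 to 0.0320 for Ddx4, −0.0800 to 0.0439 for Foxl2, −0.301 to 1.22 for Hbb-bt and −0.00275 to 0.0579 for Mki67. Medians ranged from −0.0344 to 0.0137 for aminoacyl-tRNA synthetases, −0.00674 to 0.0358 for mTOR components, −0.0305 to 0.0554 for proliferation, −0.0624 to 0.0393 for cholesterol synthesis, −0.0132 to 0.0189 for heat shock, −0.00377 to 0.0680 for p53 targets, −0.0303 to 0.00405 for extracellular matrix and −0.0639 to 0.0326 for Hippo-YAP targets. They ranged from −0.0960 to 0.403 for immediate early genes, −0.419 to 0.790 for cytokines, −0.0219 to 0.0862 for stroma and −0.0795 to 0.152 for oviduct and mesonephric epithelium.

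At 34474821 to 38002135 reads per library and 3 libraries per group, the fit found 73 of 100 genes simulated with a log2 change of 0.5, so some changes of that size were not detectable. Smaller changes were not simulated. The simulated noise was independent between genes and 200 genes were changed, so the share found may differ in the real data. There Rpl21 at −1.15 and Vegfa at 0.69 did not pass.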

Other observations

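The tests chosen only after the result was seen were all counts over other splits of the libraries, voom on the recovered reads, the length trend without ribosomal and respiratory genes, the effects of length and of the immediate early score on the hypoxia, glycolysis and ER lists, and the comparison of small nucleolar RNA (snoRNA) host genes with ribosomal proteins. The genes and lists named in the next 2 paragraphs were also chosen after their values were seen.

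Gas5 and the Snhg-named genes, which host snoRNAs in their introns, were higher in ISRIB. All 15 measured had a positive log2 fold change, with a median of 0.37. Of these, 11 had every ISRIB library above every Control library and 0 every one below. Chance gives 10% for both directions together, and over all genes tested 22.8% did not overlap. The host genes had a median length of 628 bases, and the shortest of 10 length groups had a median log2 fold change of 0.10. Snhg1 had 58.6 ± 3.54 FPKM in Control and 79.7 ± 9.52 in ISRIB (mean ± SD over 3 libraries each) and Snhg20 had 12.9 ± 0.991 and 19.3 ± 3.66. The list was formed after Gas5 and Snhg12 had been seen among the top genes. Without these, the other 13 were all higher, with a median of 0.36, and 9 had every ISRIB library above (camera p = 2.65e-08 with a preset correlation and 0.0689 with an estimated correlation).

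Among the 120 genes that passed voom on the recovered reads, the Notch receptor genes Notch1 and Notch2 were lower, at 10.9 ± 0.464 and 23.4 ± 0.238 FPKM in Control and 8.70 ± 0.173 and 18.2 ± 0.835 in ISRIB (voom adjusted p = 0.0258 and 0.0189). The endothelial nitric oxide synthase Nos3 and the endothelial surface protein Cd93 were lower as well, with limma log2 fold changes of −0.33 and −0.35. The hexokinase Hk2 and the collagen lysyl hydroxylase Plod2 were higher, with 0.55 and 0.44, as was the mitophagy gene Bnip3 with 0.48. The antioxidant enzyme Gpx3 had 48.1 ± 3.86 and 82.7 ± 13.3 FPKM (log2 fold change 0.77). In limma each of these had an adjusted p of 0.0799 to 0.104. In voom with the length correction Notch2 and Gpx3 passed (adjusted p = 0.0412 and 0.0425), and Notch1, Nos3, Cd93, Hk2, Plod2 and Bnip3 did not, with adjusted p values of 0.0622 to 0.111. The 40 genes higher in voom had a median length of 2671 bases and the 80 lower ones 9089 bases, against 3549 bases in the genes tested.

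Longer genes tended to be lower and shorter genes higher in ISRIB, with a Spearman rho of −0.361 across genes. The trend was −0.215, −0.388 and −0.497 in genes of low, middle and high expression outside every list, so 1 length-dependent bias of the libraries, from RNA integrity or library making, could account for it. Ribosomal protein and respiratory chain genes were not its only source, since rho was −0.347 without them, and GC content was not, since rho was −0.372 after a GC trend was removed. A true shift toward short transcripts under ISRIB would look alike, and the labels give no RNA quality or batch, so treatment and handling of the 2 groups cannot be told apart as its source.

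Hypoxia-induced, glycolysis and ER chaperone genes were higher together, with a median of 0.255 over 61 members, of which 59 were higher. The trends with length and GC content cannot be the whole source, as the median was 0.234 after the length correction and 0.236 after correction for length and GC content. With the immediate early score as a covariate it was 0.257, so a stress response in ISRIB replicate 1 alone does not account for it. The treatment itself stays open, as does a response to the culture such as less oxygen in larger or denser tissue. So do a batch shared by the ISRIB libraries and a chance difference between the groups, and the design separates none of these. In camera with an estimated correlation each list had an adjusted p = 0.493.

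For these snoRNA host genes the median was 0.285 after the length correction, and 0.235 over the 13 without Gas5 and Snhg12. Before the correction their median of 0.37 lay above the upper quartile of 0.19 in the shortest of the 10 length groups. The correction took 1 trend over all genes, but that trend was steeper at high expression (rho −0.497) than at low (−0.215). It therefore cannot say how much of their difference comes from length. The median of all 15 host genes exceeded that of ribosomal protein genes, which share their promoter type, by 0.202 after the same correction. The SE of 0.0479 is over member genes, which come from the same 6 libraries and are not independent. Host genes thus rose more than ribosomal protein genes in these libraries, but the SE cannot exclude a common rise of both groups. Host transcripts such as Gas5 are degraded when translated, and less nonsense-mediated decay would raise them. The decay factors, whose own transcripts are decay targets, had a median of −0.0289 (SE 0.0244 over 7 genes). That argues against less decay in these libraries, with an SE over genes and not over samples. The treatment, a common rise with ribosomal protein genes and a batch shared by the ISRIB libraries stay open. So do the trend with length and a chance difference between the groups (camera p = 0.0550 with an estimated correlation over all 15).

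The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. At an unadjusted p under 0.05 the real split gave 2125 genes and the highest other split 890, and 1 of the 10 splits gave as many as the real one. For adjusted p under 0.05 the real split gave 0 genes in limma and the highest other 1, so all 10 splits gave as many, and in voom 120 and 0, so 1 did. For lists past camera with a preset correlation the real split gave 12 and the highest other 18, and 6 of the 10 splits gave at least 12.

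Along the first principal component (33.38% of the variance) ISRIB replicate 1 at 15.83 and ISRIB replicate 3 at −13.99 lay farthest apart, and along the next (30.31%) the Control libraries were positive and the ISRIB libraries negative. Inflammatory cytokine scores deviated from the mean of the 6 libraries by −0.64, 0.40 and −0.26 in Control and 1.39, −0.24 and −0.67 in ISRIB.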
